A study of Mus musculus with 17 samples.

How the data were processed

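RNA from 17 libraries of DN2 and DN3a thymocytes was analysed, in 6 groups by genotype, stage and age, all from C57BL/6 mice per the labels. Per the labels' protocols, RNA was prepared with RNeasy Plus Micro kits and made into TruSeq libraries, which were sequenced as single-end reads of 100 bases on a HiSeq instrument. The deposited values are raw counts of reads per gene for 27179 Entrez gene identifiers, made by the authors with featureCounts on mm10, per the submitters' processing notes. The aligner, the gene annotation and the strand of the libraries are not given in the sources used here, so reads of overlapping or adjacent genes and of near-identical relatives cannot be assigned with certainty. The count files of all 17 single libraries equalled the columns of the combined table. A further wild-type young DN2 library that the design speaks of is not analysed here. Identifiers were named from the RefSeq table (25275) and from GENCODE tables (18), and 1886 stayed unnamed, with 0.947 to 19.9% of a library's reads. Among these the feature 100861531 held 0.306 to 16.6%, over 8% in 4 libraries. Coordinates are from GRCm38.

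Libraries held 7183303 to 11360308 counted reads, so that a single read equals 0.0880 to 0.139 CPM. Of 18760 genes with a read, 13534 passed edgeR's filter (minimum count 10, minimum total 15) and were tested. Pairs of libraries within a group had log CPM correlations of 0.953 to 0.988. Their squared differences were 13.1 to 161 times the counting variance (chi-square per degree of freedom). The common biological coefficient of variation was 0.244. Groups and comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood over all libraries with 1 mean per group, and 9 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The contrasts were transgenic against wild-type in young DN2, young DN3a and old DN3a, DN3a against DN2 in young mice of each genotype, old against young DN3a in each genotype, and the 2 interactions of genotype with stage and with age. Log CPM used a prior count of 2.

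The 33 fixed gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists, with the correlation estimated per list as an alternative. A second alternative was fry, which tests whether the genes of a list on balance move 1 way and does not compare them with other genes. The lists hold 678 genes, 70 of them on several lists, so the lists are not independent. The list of mitochondrially encoded genes was made by a symbol pattern that also took in the nuclear genes Grpel1, Grpel2, Hspe1, Tk2 and Trnt1, and it was kept as fixed. Named genes are Lmo2, the 8 genes with the largest fold in each direction for each genotype comparison, 6 for stage and age and 5 for interactions, the 10 shared genes with the largest smallest fold, and up to 4 called members of each list with any of its first 3. Some results for genes that this rule names are not reported here. The largest folds were taken among called genes with a mean of at least 5 CPM in the higher group, without predicted symbols or receptor segments, and, except for interactions, with no overlap between the libraries of the groups. That rule alone makes large folds the ones named, and 20% of genes that do not differ would part this way by chance with 3 against 2 libraries, or 10% with 3 against 3. Where a group had no read, a bound on the fold was computed from 3 counts over the group, and where it had 1 to 3 reads, an exact 95% interval for the ratio.

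The stage sets were genes called between wild-type young DN2 and DN3a at 2-fold or more in a fit of these 5 libraries alone (598 calls), not in the fit of all libraries. Of the 6 young DN3a libraries, 5 come from mice that also gave a DN2 library, and wild-type young DN3a replicate 3 does not. The replicate numbers in the titles do not follow the mouse in the transgenic groups. The same mouse's deviations from the group means correlated at -0.07 to 0.18 between stages, over 0.1 in 1 of 5 mice, so the mouse was not used as a block in the reported fit. The alternatives tried were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no filter, a fit of only the groups compared, library letter or sex as covariate, blocks by mouse or by replicate number, and leaving out each library. Further ones were chosen after the data were seen: the log2 share of the unnamed feature as a covariate, removal of that feature with Lars2 and mitochondrial genes, and fits without the libraries rich in that feature or without male mice.

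The procedure was tested on simulated counts with 50 genes planted per fold size in each of 9 comparisons of 13145 to 13211 genes. It recovered 0 to 10% of genes planted at 1.5-fold, 8 to 52% at 2-fold, 52 to 86% at 4-fold and 68 to 94% at 8-fold, with 3 to 8 calls outside the planted genes. All 9 planted lists of 25 genes were called by camera, with 1 other list. Genes were simulated independently and lists drawn at random, so this does not test list calls where the genes of a list correlate.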

Results

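Gene expression was measured by RNA sequencing in thymocytes of wild-type C57BL/6 mice and of mice of the same strain that carry an Lmo2 transgene. Lmo2 encodes a LIM-only bridging protein of stem and progenitor cells that is normally switched off as thymocytes commit to the T lineage. DN2 and DN3a are successive stages of the CD4 and CD8 double-negative phase, in which thymocytes commit to the T lineage and then rearrange the T cell receptor beta locus. DN2 and DN3a cells came from young mice aged 2.5 to 3 weeks, and DN3a cells also from old mice aged 6 to 10 weeks. The 17 libraries form 6 groups. Young DN2 has 2 wild-type and 3 transgenic libraries, and each of the 4 DN3a groups has 3. Counted reads per library were 11360308 and 9753107 in wild-type DN2 and 10056479, 7183303 and 8302871 in transgenic DN2. They were 10521134, 9411716 and 10143236 in wild-type and 7678141, 8155099 and 10076127 in transgenic young DN3a, and 8365727, 9175187 and 8457234 in wild-type and 9553329, 10799084 and 9880368 in transgenic old DN3a. Wild-type DN2 replicate 1 stood apart, with reads in 13028 genes despite the largest total, against 14447 to 15680 genes in the other libraries.

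The SE of a fold is its absolute log2 fold change divided by the square root of edgeR's quasi-likelihood F statistic. Below, a value in parentheses after a gene is its log2 fold change from edgeR ± that SE. Where the lower group had no read, it is the smallest fold that 3 counts over that group allow, and where that group had 1 to 3 reads it is the ratio of CPM (counts scaled to library size) with its 95% counting interval. Levels are mean CPM ± SD over the libraries of a group, with n = 2 in wild-type DN2 and n = 3 elsewhere. "Higher", "lower", "rose" and "fell" are used of genes with a Benjamini-Hochberg adjusted p under 0.05 over 13534 genes. Adjusted p-values of gene lists are from camera over 33 lists. Bounds and counting intervals cover counting error only, not the spread between mice.

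The first question was whether the transgenic libraries express Lmo2 (Entrez gene 16909, chromosome 2, 103957903 to 103981878, GRCm38). Lmo2 stood at 119 ± 33.2 CPM in transgenic DN2, 35.5 ± 3.84 CPM in transgenic young DN3a and 24.9 ± 4.63 CPM in transgenic old DN3a. In wild-type libraries it stood at 0.201 ± 0.284, 0.282 ± 0.166 and 0.319 ± 0.461 CPM in the same settings, which rests on 4, 9 and 9 reads. Every transgenic library lay above every wild-type library. The log2 fold change was 9.20 ± 0.69 in young DN2, 6.92 ± 0.54 in young DN3a and 6.16 ± 0.54 in old DN3a, with adjusted p of 1.37e-07, 1.94e-07 and 1.72e-07. Between stages, Lmo2 fell in transgenic cells from DN2 to DN3a (-1.74 ± 0.35, adjusted p = 0.00109). From young to old transgenic DN3a it moved by -0.52 ± 0.34 (adjusted p = 0.381) and did not pass the test. Xist and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y matched the labelled sex in 17 of 17 libraries. Of these 5 sex genes, 0 differed by genotype in any of the 3 settings with edgeR, 0 at an unadjusted p under 0.05, and 0 with DESeq2 or limma voom.

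**Figure D1:**
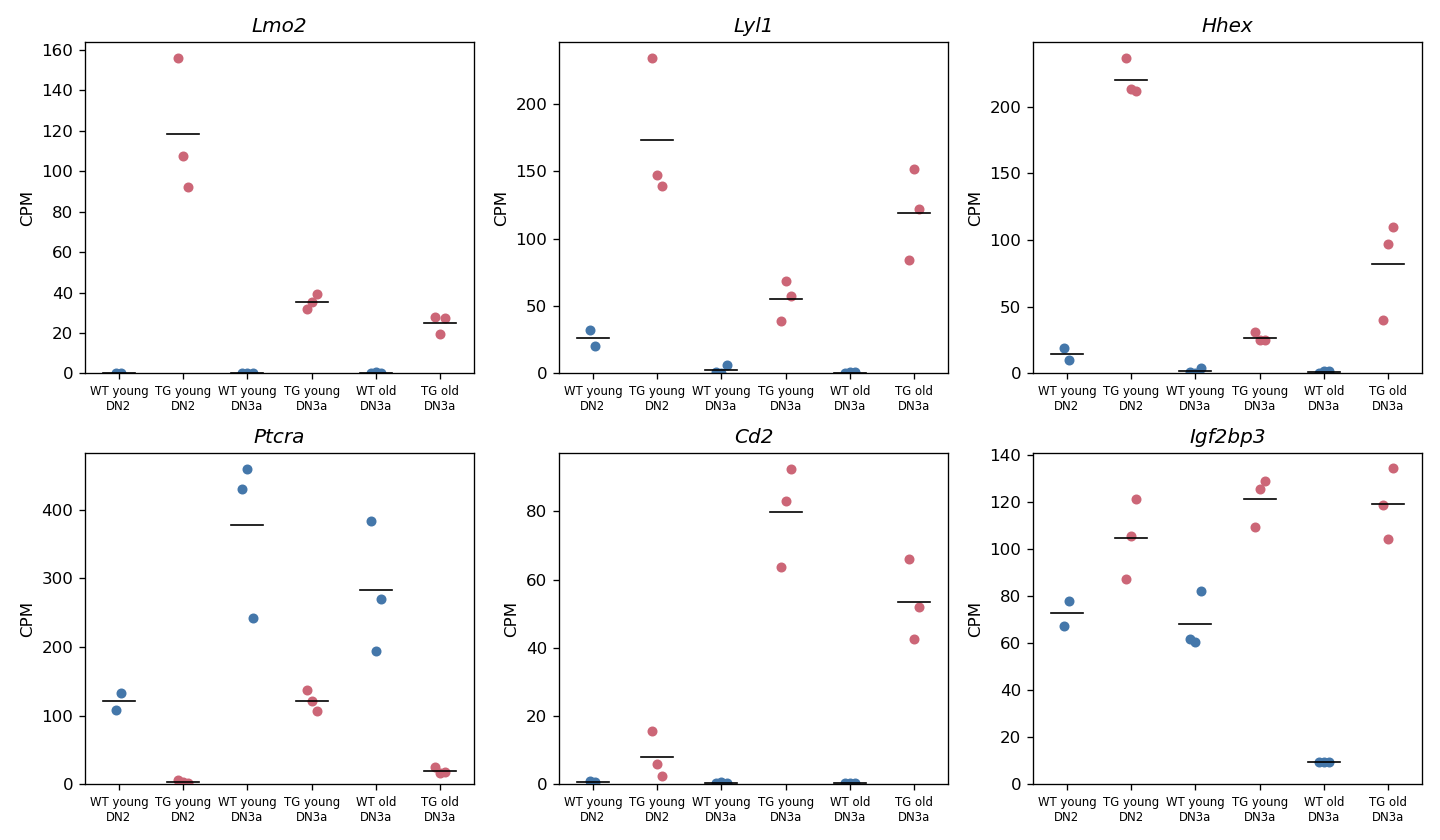
Level in CPM (linear vertical axis) of Lmo2, Lyl1, Hhex, Ptcra, Cd2 and Igf2bp3 in each library, by group, with wild-type libraries in blue, transgenic libraries in red and a bar at each group mean. Lmo2 averaged 119 CPM in transgenic DN2 and 0.201 CPM in wild-type DN2.

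The comparison of transgenic with wild-type young DN2 cells asks what the transgene changes at the earlier stage. Genes of the T cell receptor machinery were lower in transgenic DN2. Ptcra, which encodes the pre-T cell receptor alpha chain, stood at 4.0 ± 2.2 CPM against 121 ± 16.8 in wild-type, a log2 fold change of -4.87 ± 0.40 (adjusted p = 5.43e-07). The CD3 chains, which carry the receptor's signal, were lower too: Cd3g (-4.22 ± 0.32), Cd3e (-3.36 ± 0.27) and Cd3d (-3.31 ± 0.39). Among T lineage commitment and pre-TCR genes, 13 of 25 genes (16 adjusted over the list alone) were lower and 3 higher, Cd2 among the latter (3.36 ± 0.60). Bcl11b, a regulator of commitment, moved by -0.48 ± 0.19 (adjusted p = 0.0669). The list was lower as a whole by camera (adjusted p = 0.00014, or 0.108 with an estimated correlation). Of genes regulated by E proteins, the basic helix-loop-helix factors that LMO2 complexes contain, 9 of 17 genes (12 adjusted over the list alone) were lower (adjusted p = 1.56e-06, or 0.0751 with an estimated correlation). Beta selection and double positive genes included Ctla4 (-3.69 ± 0.65) among 8 of 19 genes (9 adjusted over the list alone) that were lower. The early response genes Egr1 (3.05 ± 0.95) and Nr4a1 (2.97 ± 0.79) were among 3 that were higher, and the list was lower as a whole (adjusted p = 0.0433, or 0.278 with an estimated correlation).

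Regulators of stem cells and of early T progenitors were higher in transgenic DN2. The homeobox gene Hhex stood at 220.3 ± 13.9 CPM against 14.4 ± 6.36 (3.93 ± 0.67). Lyl1, a basic helix-loop-helix partner of LMO2, stood at 173 ± 52.7 against 26.3 ± 8.64 (2.72 ± 0.61). Spi1, which encodes the myeloid and early progenitor factor PU.1, was also higher (3.10 ± 0.70), as were Gfi1b (3.46 ± 0.63) and Cd34 (3.06 ± 0.96). Of early T progenitor regulators 11 of 19 genes (14 adjusted over the list alone) were higher (adjusted p = 2.09e-06, or 0.0658 with an estimated correlation). So were 8 of 17 genes (8 adjusted over the list alone) of the stem and progenitor list (adjusted p = 0.0083, or 0.272 with an estimated correlation). The 2 lists share 6 members. Markers of other blood lineages moved with these regulators. Myeloid genes were higher in 5 of 11 genes (6 adjusted over the list alone, camera adjusted p = 0.0002, or 0.04 with an estimated correlation). Among them were Mpo (4.73 ± 0.50), a peroxidase of granulocyte precursors, Itgam (4.37 ± 0.49) and Ctsg (at least 22.0-fold). Lyz2, a marker of mature myeloid cells, moved by 0.80 ± 0.35 (adjusted p = 0.099). Natural killer and innate lymphoid genes were higher in 6 of 13 genes (8 adjusted over the list alone) and lower in 2 (adjusted p = 0.000601, or 0.04 with an estimated correlation). The higher ones included Gzmb (at least 265-fold), a protease of cytotoxic granules, Il18r1 (at least 17.1-fold) and Zbtb16 (4.69 ± 1.07). Megakaryocyte and platelet genes were higher in 5 of 8 genes (6 adjusted over the list alone), among them F2r (3.07 ± 0.50) and Nfe2 (2.44 ± 0.35) (adjusted p = 0.00123, or 0.0474 with an estimated correlation). Their median was 1.70, or 1.46 with genes without reads at their bound.

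Cell cycle, biosynthesis and mitochondrial transcripts were lower in transgenic DN2. All 26 tested G2 and M phase genes were lower (26 adjusted over the list alone), with a median log2 fold change of -2.18. So were 20 of 25 genes (23 adjusted over the list alone) of the S phase list, median -1.28. Mki67, a marker of cycling cells, stood at 307 ± 97.6 CPM against 1894 ± 115 (-2.63 ± 0.51), and so was Tyms (-2.17 ± 0.29), the thymidylate synthase gene. For G2 and M phase camera gave adjusted p = 2.87e-12, or 0.28 with an estimated correlation. For S phase it gave adjusted p = 4.59e-10, or 0.278 with an estimated correlation. MYC targets in ribosome biogenesis were lower in 13 of 22 genes (14 adjusted over the list alone, camera adjusted p = 1.56e-06, or 0.0819 with an estimated correlation), with Gnl3 (-1.25 ± 0.27) and Myc (-1.20 ± 0.24). Cholesterol synthesis genes were lower in 15 of 20 genes (16 adjusted over the list alone, camera adjusted p = 3.2e-07, or 0.0872 with an estimated correlation), with Cyp51 (-1.5 ± 0.20) and Dhcr7 (-1.30 ± 0.19). Ribosomal protein genes were lower in 16 of 88 genes (10 adjusted over the list alone, camera adjusted p = 0.000274, or 0.605 with an estimated correlation). On the mitochondrial chromosome 13 of 15 tested transcripts were lower, with mt-ND5 at 2344 ± 378 CPM against 14500 ± 1483. The list by symbol pattern, which also takes in 5 nuclear genes, was lower as a whole (adjusted p = 3.2e-07, or 0.278 with an estimated correlation). Mitochondrial transcripts made up 12.8 ± 0.867% of reads in wild-type and 2.65 ± 0.956% in transgenic DN2. An unnamed feature of 5868 bases took 0.972 ± 0.513% of reads in wild-type and 10.95 ± 6.52% in transgenic DN2. Interferon response genes were higher in 13 of 20 genes (15 adjusted over the list alone), led by Rsad2 (2.94 ± 0.44) (adjusted p = 3.58e-05, or 0.318 with an estimated correlation). Early response genes, which cell dissociation can also induce, were higher in 5 of 17 genes (5 adjusted over the list alone), led by Zfp36 (3.48 ± 0.88) (adjusted p = 0.0326, or 0.605 with an estimated correlation).

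**Figure D2:**
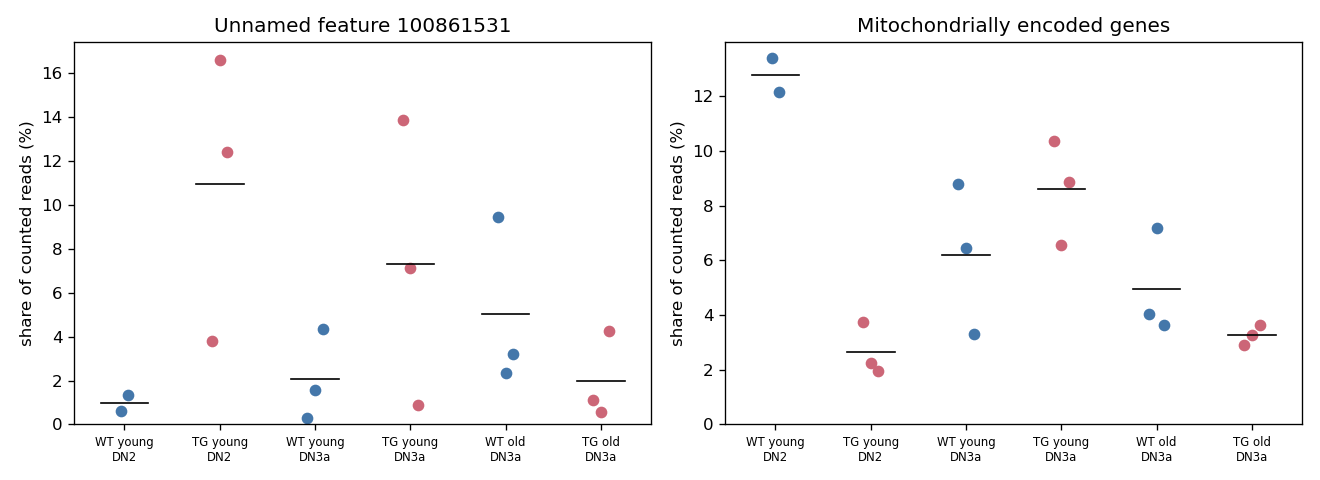
Share of counted reads in percent per library, by group, in the unnamed feature (left) and in mitochondrial transcripts (right). The feature held 10.95% on average in transgenic DN2 and 0.972% in wild-type DN2.

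The genes with the largest folds higher in transgenic DN2 were Gzmb (at least 265-fold), Aox1 (at least 172-fold), Lrrc4b (at least 62.3-fold), Lmo2, St8sia6 (at least 46.4-fold), Tenm4 (154-fold, 27.6 to 6076), Scn11a (119.9-fold, 41.0 to 582) and Itga2 (112-fold, 20.1 to 4428). Aox1 encodes an aldehyde oxidase and Itga2 an integrin subunit that binds collagen. The genes with the largest folds lower were Adamtsl2 (47.6-fold, 16.3 to 231), Slc5a9 (-5.29 ± 0.78), Epha2 (-5.05 ± 0.84), Ptcra, Cldn4 (-4.60 ± 0.74), Col15a1 (-4.54 ± 0.50), Khdc1c (-4.43 ± 0.57) and Zcchc12 (-4.39 ± 0.68). Among receptors of cytokines and of homing signals, the interleukin 7 receptor gene Il7r (-2.92 ± 0.20) was lower, as were Ifngr1 (-3.04 ± 0.21) and Ccr9 (-3.46 ± 0.57), while Il4ra (2.45 ± 0.39) and the integrin subunit Itgb7 (4.67 ± 0.38) were higher. The lists as wholes did not pass camera. Cytokine receptors had 5 higher and 3 lower of 20 (5 and 3 adjusted over the list alone), and chemokine receptors and adhesion genes 3 higher and 6 lower of 17 (3 and 7 adjusted over the list alone). Neither did the LMO2 complex and partners with 4 higher and 3 lower of 16 (5 and 3 adjusted over the list alone), or Notch pathway targets with 3 higher and 4 lower of 15 (4 and 4 adjusted over the list alone). Gamma delta T cell genes had 2 higher and 3 lower of 12 (2 and 5 adjusted over the list alone). Cell cycle inhibitors had 4 higher and 2 lower of 19 (5 and 3 adjusted over the list alone). Mature alpha beta T cell genes had 5 higher and 6 lower of 19 (5 and 6 adjusted over the list alone). Of other lineages, erythroid genes had 3 higher and 1 lower of 9 (3 and 1 adjusted over the list alone). Mast cell and basophil genes had 2 higher and 0 lower of 7 (3 and 0 adjusted over the list alone), and B cell genes 2 higher and 2 lower of 12 (2 and 3 adjusted over the list alone). Dendritic cell and MHC class II genes had 3 higher and 1 lower of 12 (3 and 1 adjusted over the list alone), and thymic stroma genes 2 higher and 3 lower of 7 (2 and 3 adjusted over the list alone). None of these lists passed camera.

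In all, 3426 of 13534 genes differed between transgenic and wild-type young DN2, 1797 higher and 1629 lower. The count was 1535 without wild-type DN2 replicate 1, and 2177 and 2261 without transgenic DN2 replicates 2 and 3. It was 1413 with the share of the unnamed feature as a covariate. Leaving out the libraries that hold over 8% of it keeps 1 transgenic DN2 library, at 3.81% against 16.6 and 12.4% in the others. No count is given for that fit.

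Of 55 called genes named in the text, 44 kept their call without each single library. Adamtsl2, Cd34, Cpeb1, Egr1, Kcns3, Nr4a1, Pwwp3b, St8sia6, Tmem45a, Ttf2 and Zfp36 lost it without at least 1 of wild-type DN2 replicates 1 and 2 and transgenic DN2 replicates 1, 2 and 3.

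The comparison in young DN3a asks the same of the later stage in mice of the same age. Several surface proteins and regulators that were almost silent in wild-type young DN3a were expressed in transgenic cells. Cd2, an adhesion molecule of T cells, stood at 79.8 ± 14.6 CPM against 0.506 ± 0.265 (7.28 ± 0.55, adjusted p = 1.94e-07). P2rx7, an ATP-gated channel, stood at 111 ± 18.1 against 0.38 ± 0.208 (8.16 ± 0.36), and Mdga1 at 279.7 ± 52.0 against 2.00 ± 2.17 (7.11 ± 0.46). The other genes with the largest folds higher were Podxl (869-fold, 298 to 4216), Tmem45a (at least 77.8-fold), Bmpr1a (494-fold, 88.7 to 19510), Tbx4 (350.2-fold, 119.8 to 1698) and H2-Q2 (7.21 ± 0.58). H2-Q2 belongs to a family of near-identical genes between which reads can be split, so its value is uncertain. Those with the largest folds lower were Angptl7 (-4.76 ± 0.74), Mef2c (-4.19 ± 0.57), Epha2 (-3.61 ± 0.74), Gpr55 (-3.44 ± 0.62), Adamtsl2 (-3.42 ± 0.72), Atoh8 (-3.27 ± 0.44), St6galnac3 (-3.27 ± 0.43) and Tdrd5 (-3.25 ± 0.35). Bmpr1a encodes a receptor of bone morphogenetic proteins, and Mef2c a transcription factor of early lymphoid progenitors.

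The progenitor regulators split in young DN3a. Lyl1 (4.37 ± 0.61) and Hhex (3.94 ± 0.64) were higher, while Mef2c, Bcl11a (-2.70 ± 0.45), Hoxa7 (-3.18 ± 0.41) and Hoxa5 (-1.68 ± 0.43) were lower. Spi1 moved by -0.80 ± 0.76 (adjusted p = 0.586). Early T progenitor regulators had 5 higher and 5 lower of 19 (6 and 7 adjusted over the list alone). Stem and progenitor genes had 5 higher and 3 lower of 17 (5 and 6 adjusted over the list alone), and neither list passed camera. Genes regulated by E proteins were lower in 7 of 17 genes (9 adjusted over the list alone, camera adjusted p = 0.000322, or 0.208 with an estimated correlation). They included Ptcra (-1.63 ± 0.31), the recombinase gene Rag2 (-1.56 ± 0.26) and Cdkn1a (-2.55 ± 0.50), whereas the coreceptor gene Cd8a (4.11 ± 0.65) was higher. Mature alpha beta T cell genes were higher in 8 of 19 genes (8 adjusted over the list alone, camera adjusted p = 0.000404, or 0.0842 with an estimated correlation). They included Itgb7 (4.03 ± 0.33), Cd8b1 (3.78 ± 0.71) and the migration regulator Klf2 (3.55 ± 0.51). Dendritic cell and MHC class II genes were lower in 5 of 12 genes (7 adjusted over the list alone, camera adjusted p = 7.06e-05, or 0.017 with an estimated correlation), with Irf8 (-2.63 ± 0.41) and H2-DMa (-1.83 ± 0.25). B cell genes were lower in 4 of 12 genes (4 adjusted over the list alone, camera adjusted p = 0.0471, or 0.208 with an estimated correlation), with Spib (-1.84 ± 0.29) and Ly6d (-1.61 ± 0.24). Megakaryocyte and platelet genes were higher in 3 of 8 genes (3 adjusted over the list alone, camera adjusted p = 0.0451, or 0.208 with an estimated correlation), with F2r (4.0 ± 0.44) and Itgb3 (2.09 ± 0.24). The mast cell protease Cpa3 (3.93 ± 0.80) was higher, in a list with 2 higher and 0 lower of 7 (3 and 1 adjusted over the list alone) that did not pass camera.

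S phase genes were higher in transgenic young DN3a in 9 of 25 genes (14 adjusted over the list alone), median 0.72, with Ccne1 (1.48 ± 0.42) and Cdc6 (1.16 ± 0.29) (adjusted p = 1.18e-06, or 0.502 with an estimated correlation). For G2 and M phase genes camera gave a higher direction (adjusted p = 0.00129, or 0.764 with an estimated correlation) with a median of 0.60. Of single members, 0 of 26 members passed in edgeR, 3 at an unadjusted p under 0.05, 0 with DESeq2 and 23 with limma voom. MYC targets were higher in 3 of 22 genes (5 adjusted over the list alone), with Rrp12 (1.05 ± 0.20) (adjusted p = 0.00129, or 0.361 with an estimated correlation). Camera also gave a higher direction for replication dependent histone genes (adjusted p = 0.00158, or 0.688 with an estimated correlation). They had 1 higher and 1 lower of 34 (4 and 2 adjusted over the list alone), and their many copies share sequence and are uncertain one by one. Camera's direction was also higher for the mitochondrial list, which holds 5 nuclear genes (adjusted p = 0.00129, or 0.707 with an estimated correlation). So it was for ribosomal protein genes (adjusted p = 0.0319, or 0.764 with an estimated correlation). In these 2 lists, 0 and 0 passed in edgeR, 6 and 9 higher at an unadjusted p under 0.05, 3 and 1 with DESeq2, and 3 and 2 with limma voom. Mitochondrial transcripts took 6.18 ± 2.75% of reads in wild-type and 8.60 ± 1.92% in transgenic young DN3a. The unnamed feature took 2.08 ± 2.08% and 7.30 ± 6.50%. Cell cycle inhibitors went both ways, with Cdkn2a (at least 14.3-fold) and Cdkn2c (2.28 ± 0.34) higher and Cdkn1a lower, in a list with 5 higher and 5 lower of 19 (5 and 5 adjusted over the list alone).

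In young DN3a 1334 genes differed, 636 higher and 698 lower. The count was 3692 with limma voom, 782 without wild-type young DN3a replicate 1 and 737 without replicate 2.

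Of 48 called genes named in the text, 44 kept their call without each single library. Ccne1, Cdc6, Hoxa5 and Ttf2 lost it without at least 1 of wild-type young DN3a replicates 1, 2 and 3 and transgenic young DN3a replicates 1, 2 and 3.

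In old DN3a the comparison asks what the transgene changes in older mice. The progenitor regulators Lyl1 and Hhex were again higher, with Lyl1 at 119 ± 33.7 CPM against 0.660 ± 0.381 (7.44 ± 0.75, adjusted p = 6.86e-06) and Hhex at 82.3 ± 37.0 against 1.23 ± 1.01 (6.01 ± 0.70). Their folds were larger than in young DN3a, but the difference did not pass the interaction test (adjusted p = 0.128 and 0.287). In simulated counts that test recovered 66% of genes planted at 4-fold, so equal effects are not shown. The young folds also depend on wild-type young DN3a replicate 3, with Lyl1 at 6.34 and Hhex at 3.95 CPM. Replicates 1 and 2 had 1.07 and 0.495 CPM of Lyl1 and 0.805 and 0.396 CPM of Hhex. Among transgenic DN3a libraries, every old one lay above every young one for both genes. Other regulators were close to silent in transgenic cells: Hoxa5 (at least 69.7-fold), Hoxa7 (398-fold, 71.5 to 15740), Mef2c (at least 63.1-fold) and Bcl11a (-6.84 ± 0.63) were lower. Early T progenitor regulators had 4 higher and 8 lower of 19 (4 and 9 adjusted over the list alone). Stem and progenitor genes had 6 higher and 6 lower of 17 (7 and 7 adjusted over the list alone), and neither list passed camera. Highest by fold were Tspan32 (at least 199-fold), Acnat1 (at least 92.9-fold), Kcns3 (at least 58.0-fold), Cpeb1 (at least 57.4-fold), Il5ra (at least 50.8-fold), Ryr2 (429.5-fold, 77.1 to 16960), Tbx4 (8.32 ± 0.97) and Slc7a8 (7.99 ± 0.62). Il5ra encodes the interleukin 5 receptor alpha chain and Ryr2 a calcium release channel. Lowest by fold were Hoxa5, Tmtc2 (at least 65.5-fold), Krt87 (at least 64.3-fold), Mef2c, Tceal8 (at least 56.2-fold), Arhgap32 (419-fold, 143 to 2031), Scel (461-fold, 82.7 to 18200) and Fam163b (-8.15 ± 0.91).

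Genes of cell division were higher in transgenic old DN3a. S phase genes were higher in 23 of 25 genes (23 adjusted over the list alone), median 1.46, with Rrm2 (2.49 ± 0.41) and Cdc45 (2.36 ± 0.29) (adjusted p = 4.8e-11, or 0.593 with an estimated correlation). G2 and M phase genes were higher in 24 of 26 genes (26 adjusted over the list alone), median 1.88, with Hmmr (2.37 ± 0.51) and Plk1 (2.29 ± 0.36) (adjusted p = 4.83e-10, or 0.611 with an estimated correlation). MYC targets were higher in 6 of 22 genes (6 adjusted over the list alone), with Ldha (1.32 ± 0.21) and Bop1 (1.07 ± 0.24) (adjusted p = 0.013, or 0.593 with an estimated correlation). The tumour suppressor transcript Cdkn2a was higher (200-fold, 35.9 to 7900) and the inhibitor Cdkn1a lower (-3.90 ± 0.54), in a list with 5 higher and 3 lower of 19 (7 and 3 adjusted over the list alone). Genes regulated by E proteins were lower in 10 of 17 genes (12 adjusted over the list alone, camera adjusted p = 0.00115, or 0.593 with an estimated correlation). They included Ptcra (-3.82 ± 0.34) and Cd3g (-2.18 ± 0.28), whereas Cd8a (5.88 ± 0.76) was again higher. Dendritic cell and MHC class II genes were lower in 7 of 12 genes (8 adjusted over the list alone, camera adjusted p = 0.00224, or 0.0911 with an estimated correlation), with H2-DMa (-3.79 ± 0.28) and H2-DMb1 (-4.55 ± 0.51). Of the lists that did not pass, mature alpha beta T cell genes had 8 higher and 5 lower of 19 (9 and 5 adjusted over the list alone), with Trac (4.57 ± 0.55). Notch pathway targets had 3 higher and 5 lower of 15 (3 and 5 adjusted over the list alone), with Notch3 (-2.13 ± 0.32). Interferon response genes had 0 higher and 8 lower of 20 (1 and 8 adjusted over the list alone), with Ifi44 (153-fold, 52.4 to 743). Cytokine receptors had 5 higher and 5 lower of 20 (6 and 5 adjusted over the list alone), with Csf2ra (-4.67 ± 0.81). Megakaryocyte and platelet genes had 4 higher and 2 lower of 8 (4 and 2 adjusted over the list alone), with F2r (4.5 ± 0.45). The unnamed feature took 5.01 ± 3.89% of reads in wild-type and 1.99 ± 2.00% in transgenic old DN3a. Mitochondrial transcripts took 4.96 ± 1.93% and 3.28 ± 0.368%.

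In old DN3a 4146 genes differed, 2021 higher and 2125 lower, a count that stayed within 1.5 times under every alternative run. All 47 called genes named in the text also passed without each single library in turn.

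Across settings, the transgene's effect in young DN3a resembled that in old DN3a more than that in DN2. Of the genes higher in young DN3a, 510 were also higher in old DN3a, where independent lists would share 94.97. Among genes lower in young DN3a, 515 were also lower, against 109.6. Lower in old but higher in young were 2 genes, and the reverse held for 5. Log2 fold changes over 13534 genes correlated with Pearson r = 0.618 and Spearman rho = 0.519 between young and old DN3a, whose control libraries are separate. Between young DN2 and young DN3a r was 0.214 and rho -0.037. There, 198 genes were higher in both (independent lists 84.5), 181 lower in both (84.0), 119 higher in DN2 but lower in young DN3a (92.7) and 137 lower in DN2 but higher in young DN3a (76.6). Between young DN2 and old DN3a r was 0.049 and rho -0.055. Here 384 genes were higher in both (268), 284 lower in both (256), 492 lower in DN2 but higher in old DN3a (243), and 304 higher in DN2 but lower in old DN3a (282). Genes are not independent replicates, so these correlations carry no p. Of 504 genes called in all 3 settings, 312 had the same direction in each, 166 of them higher (independent lists 12.6) and 146 lower (13.2). The shared genes with the largest smallest fold in the 3 settings were Lmo2, Slc22a4, Tenm4, Kcns3, Pwwp3b, Cpeb1, Atp8a2, Clec4d and Tmem45a, all higher, and Macc1, lower. The flippase gene Atp8a2 had log2 fold changes of 5.65 ± 0.56, 5.36 ± 0.37 and 7.60 ± 0.41 in young DN2, young DN3a and old DN3a, and stood at 149 ± 45.7 CPM in transgenic old DN3a. Slc22a4, which encodes an organic cation transporter, was higher in DN2 (at least 7.53-fold), young DN3a (116-fold, 32.1 to 958) and old DN3a (141-fold, 48.1 to 682), and so was Tenm4 (65.6-fold, 22.5 to 318 in young and 7.42 ± 0.65 in old DN3a). In DN2, Kcns3 (at least 5.21-fold), Pwwp3b (at least 5.21-fold), Cpeb1 (at least 4.06-fold) and Tmem45a (at least 2.90-fold) had no read in wild-type cells. The C-type lectin gene Clec4d (at least 9.13-fold) had none in wild-type young DN3a, and Macc1 (at least 9.62-fold) none in transgenic old DN3a.

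**Figure D3:**
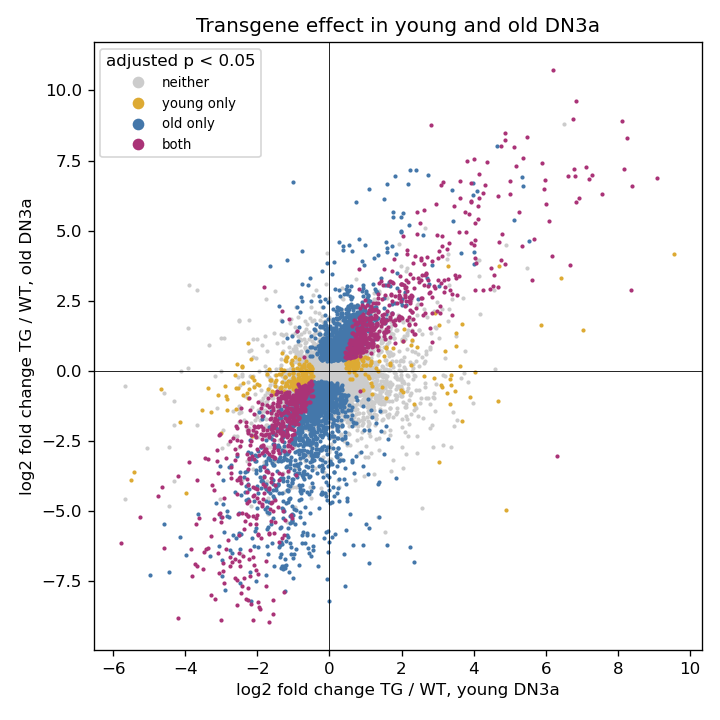
Log2 fold change of transgenic over wild-type per gene in young DN3a (horizontal axis) and old DN3a (vertical axis), coloured by whether edgeR's adjusted p was under 0.05 in neither, young only, old only or both. Points lie along the diagonal, with r = 0.618 over 13534 genes.

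The step from DN2 to DN3a in wild-type young mice gives the normal course against which the transgenic one is read. The recombinase gene Rag1 rose (2.12 ± 0.30) from 590.3 ± 98.7 to 2559 ± 292 CPM, with Ptcra (1.64 ± 0.36), Lef1 (2.02 ± 0.50) and Spib (1.65 ± 0.33). T lineage commitment and pre-TCR genes rose in 6 of 25 genes (10 adjusted over the list alone, camera adjusted p = 0.012, or 0.264 with an estimated correlation). Notch pathway targets rose in 4 of 15 genes (6 adjusted over the list alone) with Dtx1 (2.18 ± 0.33) and Notch3 (1.97 ± 0.37) (adjusted p = 0.0196, or 0.264 with an estimated correlation), and E protein regulated genes rose in 4 of 17 genes (8 adjusted over the list alone, camera adjusted p = 0.00549, or 0.264 with an estimated correlation). The progenitor regulators Tal1 (-3.86 ± 0.83), Lyl1 (-3.30 ± 0.63) and Hhex (-3.05 ± 0.68) fell, with the early adhesion receptor Cd44 (-2.56 ± 0.54). In all 6 of 19 genes (7 adjusted over the list alone) of the early T progenitor list fell (adjusted p = 0.0148, or 0.264 with an estimated correlation). S phase genes fell in 12 of 25 genes (17 adjusted over the list alone, camera adjusted p = 1.25e-10, or 0.264 with an estimated correlation). G2 and M phase genes fell in 15 of 26 genes (26 adjusted over the list alone, camera adjusted p = 5.33e-16, or 0.264 with an estimated correlation), with Mki67 (-2.14 ± 0.50) and Tyms (-1.60 ± 0.28). Camera also gave a lower direction for MYC targets (adjusted p = 0.0148, or 0.321 with an estimated correlation), of which 0 passed in edgeR, 4 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma voom. Ribosomal protein genes fell in 3 of 88 genes (3 adjusted over the list alone, camera adjusted p = 0.000102, or 0.527 with an estimated correlation). The mitochondrial list, which holds 5 nuclear genes, fell in 4 of 20 genes (13 adjusted over the list alone, camera adjusted p = 6.2e-06, or 0.321 with an estimated correlation). These 4 lie on the mitochondrial chromosome. Mature alpha beta T cell genes fell in 3 of 19 genes (4 adjusted over the list alone, camera adjusted p = 0.0229, or 0.264 with an estimated correlation). Highest by fold in DN3a were Igf2 (5.45 ± 0.85), Ephx3 (5.33 ± 0.93), Fat4 (5.29 ± 0.75), Rgl3 (4.63 ± 1.13), Gpr183 (4.62 ± 0.94) and Fam163b (4.56 ± 0.82). Lowest by fold were P2rx7 (-4.33 ± 0.39), Ifitm1 (-4.15 ± 1.02), Tal1, Emilin2 (-3.85 ± 0.71), Mdga1 (-3.47 ± 0.45) and Samhd1 (-3.39 ± 0.79).

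In wild-type cells 860 genes changed from DN2 to DN3a, 383 upward and 477 downward. The count rests on single libraries, at 11 without DN2 replicate 1, 1689 without DN2 replicate 2, 288 without DN3a replicate 1 and 136 without DN3a replicate 2. It was 1374 with DESeq2, 1644 with limma voom and 1529 with the library letter as a covariate. With a block by replicate number, which here pairs the 2 mice that gave both stages, it was 3514, and with a block by mouse over all young libraries 1001.

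Of 23 called genes named in the text, 3 kept their call without each single library (Fam163b, Mdga1 and P2rx7). The other 20 lost it without at least 1 of wild-type DN2 replicate 1 and wild-type young DN3a replicates 1 and 2.

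The same step in transgenic cells asks whether they follow that course. The peroxidase gene Mpo fell from 81.8 ± 14.7 CPM in DN2 to 1 read in DN3a (by 1972-fold, 354 to 77880), together with Tyrobp (-5.92 ± 0.73). In all 7 of 11 genes (7 adjusted over the list alone) of the myeloid list fell (adjusted p = 1.77e-07, or 0.00392 with an estimated correlation). Natural killer and innate lymphoid genes fell in 8 of 13 genes (8 adjusted over the list alone), with Gzmb (-6.72 ± 0.60) and Zbtb16 (42.3-fold, 14.5 to 205) (adjusted p = 1.19e-05, or 0.00533 with an estimated correlation). Early T progenitor regulators fell in 17 of 19 genes (18 adjusted over the list alone), with Spi1 (-5.94 ± 0.73) and Fes (-5.93 ± 0.35) (adjusted p = 6.72e-13, or 0.00533 with an estimated correlation). Stem and progenitor genes fell in 12 of 17 genes (13 adjusted over the list alone), with Cd34 (-5.01 ± 0.94) (adjusted p = 6.78e-06, or 0.0389 with an estimated correlation). Dendritic cell and MHC class II genes fell in 5 of 12 genes (6 adjusted over the list alone), with Itgax (245-fold, 67.8 to 2023) (adjusted p = 0.000744, or 0.0212 with an estimated correlation). T lineage genes rose, with commitment and pre-TCR genes up in 15 of 25 genes (15 adjusted over the list alone), with Ptcra (4.88 ± 0.38) and Cd3d (4.11 ± 0.39) (adjusted p = 2.05e-08, or 0.0212 with an estimated correlation). E protein regulated genes rose in 7 of 17 genes (8 adjusted over the list alone, camera adjusted p = 2.84e-06, or 0.0437 with an estimated correlation). Notch pathway targets rose in 6 of 15 genes (6 adjusted over the list alone, camera adjusted p = 0.0378, or 0.0857 with an estimated correlation), and beta selection genes rose in 10 of 19 genes (11 adjusted over the list alone), with Ctla4 (3.51 ± 0.62) (adjusted p = 0.000142, or 0.0389 with an estimated correlation). Cell cycle and biosynthesis genes rose as well, whereas the S phase, G2 and M phase, ribosomal protein and mitochondrial lists had fallen in wild-type cells. S phase genes rose in 22 of 25 genes (25 adjusted over the list alone, camera adjusted p = 2.9e-08, or 0.261 with an estimated correlation). G2 and M phase genes rose in 5 of 26 genes (4 adjusted over the list alone, camera adjusted p = 2.6e-05, or 0.555 with an estimated correlation). MYC targets rose in 18 of 22 genes (20 adjusted over the list alone, camera adjusted p = 8.24e-08, or 0.0389 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 20 genes (16 adjusted over the list alone, camera adjusted p = 1.61e-08, or 0.0389 with an estimated correlation). Ribosomal protein genes rose in 6 of 88 genes (0 adjusted over the list alone, camera adjusted p = 0.0153, or 0.815 with an estimated correlation). The mitochondrial list, which holds 5 nuclear genes, rose in 14 of 20 genes (17 adjusted over the list alone, camera adjusted p = 3.65e-06, or 0.261 with an estimated correlation). On the mitochondrial chromosome 13 of 15 rose, and of the nuclear genes 1 rose and 1 fell. Interferon response genes fell in 11 of 20 genes (13 adjusted over the list alone), with Ifit3 (-3.01 ± 0.51) (adjusted p = 7.41e-06, or 0.261 with an estimated correlation).

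Highest by fold in transgenic DN3a against DN2 were Fat4 (130-fold, 23.3 to 5133), Slc5a9 (6.29 ± 0.75), Fam163b (6.29 ± 0.95), Adamtsl2 (68.5-fold, 23.4 to 332), Scn4b (5.88 ± 0.49) and Igf2 (5.85 ± 0.68). Lowest by fold were Mpo, Rnase6 (at least 56.5-fold), Cd180 (at least 52.1-fold), Serpina3g (578-fold, 104 to 22810), Aqp9 (at least 45.7-fold) and Lrrc25 (at least 43.7-fold). Serpina3g has close relatives that share reads and is uncertain. In all 3506 genes changed, 1722 upward and 1784 downward. The count was 5874 with limma voom. Without the libraries rich in the unnamed feature 1 transgenic DN2 library is left, so that count is not given. The interaction test, which asks whether the step differs between genotypes, called 2828 genes, 1479 with the more positive step in transgenic cells and 1349 with the more negative. Ptcra was among the former (3.24 ± 0.49), with Mki67 (3.49 ± 0.68) and Il7r (3.07 ± 0.27). Among the latter were Mef2c (-4.73 ± 0.76), Mycn (-3.21 ± 0.43) and Fes (-4.37 ± 0.47). Its count was 4571 with limma voom and lower without wild-type DN2 replicate 1, where 1 wild-type DN2 library is left. The count without the libraries rich in the unnamed feature is not given, for the same reason as above. For the step in transgenic cells, all 24 called genes named in the text also passed without each single library in turn. For the interaction, of 16 called genes named in the text, 14 kept their call without each single library. Rhbdl3 and Tgfb2 lost it without wild-type DN2 replicate 1.

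**Figure D4:**
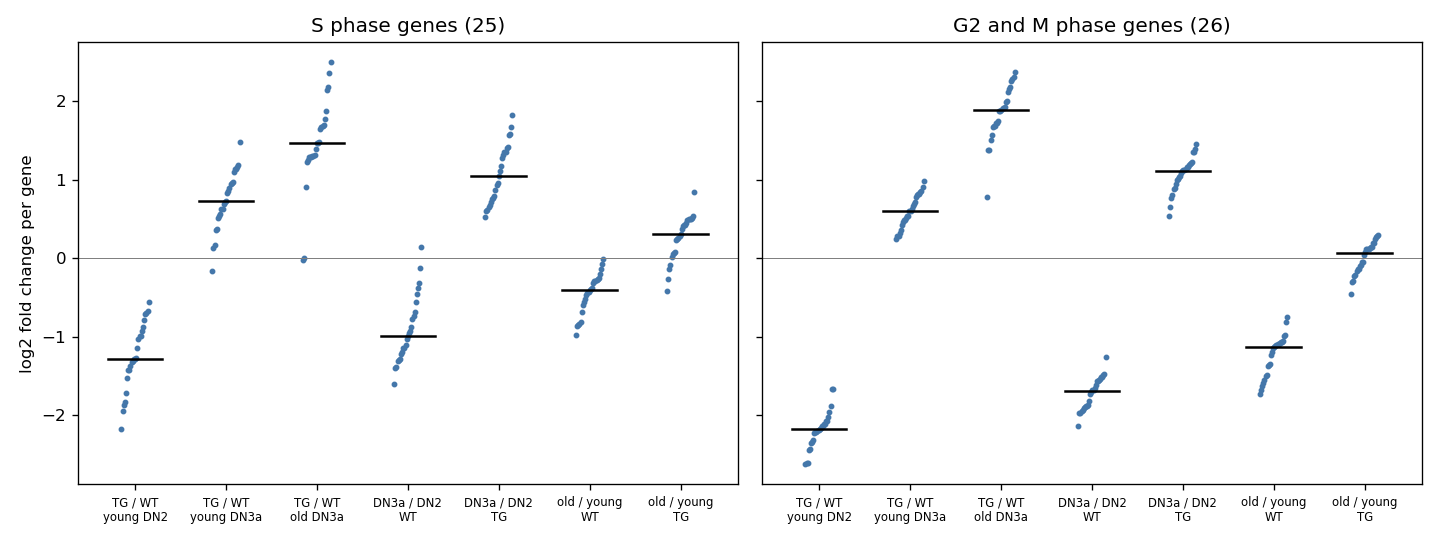
Log2 fold change of each S phase gene (left) and each G2 and M phase gene (right) in 7 comparisons, with a bar at the median of the list. For G2 and M phase the median was -2.18 for transgenic over wild-type in young DN2 and 1.88 in old DN3a.

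Age in wild-type DN3a cells, the course without the transgene, moved few genes. Igf2bp3, an RNA-binding protein of fetal and neonatal cells, fell from 68.1 ± 12.2 CPM in young to 9.58 ± 0.218 in old mice (-2.83 ± 0.18, adjusted p = 3.25e-08). The other genes with the largest folds lower in old were Chst8 (-4.5 ± 0.69), Hspg2 (-3.34 ± 0.50), Tmc5 (-3.23 ± 0.28), Izumo1r (-2.58 ± 0.47) and Arrdc4 (-2.40 ± 0.43). Highest by fold were Mid1 (4.07 ± 0.66), Fndc1 (1.82 ± 0.32), the clock gene Nr1d2 (1.22 ± 0.22), Sh2d5 (1.17 ± 0.23), H2-Q6 (4.60 ± 0.82) and H2-Q7 (3.93 ± 0.69). The last pair are near-identical relatives and uncertain. The gamma delta regulator Sox13 (-2.05 ± 0.19) fell, in a list with 1 higher and 1 lower of 12 (2 and 1 adjusted over the list alone), and so did Spib (-1.47 ± 0.29). Camera gave a lower direction for G2 and M phase genes (adjusted p = 2.12e-20, or 0.688 with an estimated correlation), median -1.14. It did so for S phase genes (adjusted p = 1.13e-07, or 0.736 with an estimated correlation), median -0.41. Of these 0 and 0 passed in edgeR (16 and 0 adjusted over the list alone). There were 23 and 6 at an unadjusted p under 0.05, 2 and 0 with DESeq2, and 0 and 0 with limma voom. It gave a lower direction for interferon response genes (adjusted p = 3.91e-05, or 0.736 with an estimated correlation). The direction was higher for cholesterol synthesis (adjusted p = 0.000305, or 0.688 with an estimated correlation) and mature alpha beta T cell genes (adjusted p = 0.0224, or 0.688 with an estimated correlation). In these 3 lists edgeR called 0 members (2, 2 and 0 adjusted over the list alone). There were 6, 4 and 3 at an unadjusted p under 0.05, 2, 2 and 0 with DESeq2, and 1, 2 and 0 with limma voom.

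In wild-type DN3a 33 genes changed with age, 14 upward and 19 downward, with 957 at an unadjusted p under 0.05. The count was 125 with DESeq2, 274 with limma voom, and 18 in a fit of these groups alone. It was 77 with the library letter as a covariate, 12 with the share of the unnamed feature as one and 14 without the libraries rich in it. It was 10, 10, 20 and 16 without young replicate 1, young replicate 2, old replicate 2 and old replicate 3. Of 14 called genes named in the text, 5 kept their call without each single library. Arrdc4, Fndc1, H2-Q6, H2-Q7, Izumo1r, Mid1, Nr1d2, Sh2d5 and Spib lost it without at least 1 of wild-type young DN3a replicates 1, 2 and 3 and wild-type old DN3a replicates 1, 2 and 3.

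In transgenic DN3a cells more genes changed with age, but there age runs partly with the library letter (a or b). All transgenic young DN3a libraries have the letter a, whereas transgenic old replicates 2 and 3 have b. In wild-type DN3a, young replicate 3 and old replicates 2 and 3 have b, so the counts of the genotypes are not directly comparable. The fetal growth factor gene Igf2 fell (-6.70 ± 0.72) from 28.5 ± 5.24 to 0.260 ± 0.375 CPM. With it Pdgfa (171-fold, 30.7 to 6749), Gab1 (155-fold, 27.8 to 6109), Arhgap32 (76.5-fold, 26.2 to 371), Fam163b (-6.06 ± 0.89) and Adam11 (-5.84 ± 0.96) had the largest folds lower. The largest folds higher were Adamts9 (5.74 ± 0.69), Ephb4 (4.29 ± 0.80), Olig3 (4.07 ± 0.56), Acox2 (3.87 ± 0.62), Aif1l (3.67 ± 0.76) and Gpr82 (3.62 ± 0.66). E protein regulated genes fell in 4 of 17 genes (5 adjusted over the list alone), with Ptcra (-2.60 ± 0.33) and Cd3g (-1.26 ± 0.28) (adjusted p = 0.038, or 0.683 with an estimated correlation). Interferon response genes fell in 4 of 20 genes (4 adjusted over the list alone), with Ifit1 (-2.08 ± 0.38) (adjusted p = 0.000596, or 0.683 with an estimated correlation). The mitochondrial list, which holds 5 nuclear genes, fell in 13 of 20 genes (16 adjusted over the list alone, camera adjusted p = 2.52e-06, or 0.683 with an estimated correlation). These 13 lie on the mitochondrial chromosome. Ribosomal protein genes fell in 7 of 88 genes (7 adjusted over the list alone, camera adjusted p = 0.000339, or 0.683 with an estimated correlation). The heat shock genes Hsph1 (1.57 ± 0.36) and Hspa8 (0.91 ± 0.19) rose, the 2 of 17 early response and dissociation stress genes that passed (4 adjusted over the list alone, adjusted p = 0.00552, or 0.683 with an estimated correlation). Camera gave a higher direction for S phase genes (adjusted p = 0.0388, or 0.731 with an estimated correlation), of which 0 passed in edgeR, 2 at an unadjusted p under 0.05, 1 with DESeq2 and 2 with limma voom. In all 1059 genes changed, 432 upward and 627 downward, a balance that turned to 589 upward and 412 downward in a fit of these groups alone and was 889 and 909 with limma voom. The count was 1798 with limma voom, 494 with the library letter as a covariate and 415 without the libraries rich in the unnamed feature. It was 456, 502 and 467 without young replicate 1, old replicate 2 and old replicate 3. Of 17 called genes named in the text, 15 kept their call without each single library. Cd3g and Hsph1 lost it without at least 1 of transgenic young DN3a replicates 1 and 2.

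The test of the difference in transgene effect between old and young DN3a called 413 genes, of which 374 (90.6%) had the larger effect in old mice. Of the 413, 380 also passed in old DN3a and 164 in young DN3a. Among them Sox13 (2.11 ± 0.26), Nfe2 (1.73 ± 0.42) and Pou2af1 (2.78 ± 0.69) had the more positive effect in old, and Ptcra (-2.19 ± 0.44) and Ctla4 (-3.32 ± 0.78) the more negative. Its count was 738 with DESeq2, 642 with limma voom and 122 without the libraries of male mice. It was 109 with the share of the unnamed feature as a covariate and 128 without the libraries rich in it. Without single libraries it ranged from 188 (without transgenic young replicate 1) to 605 (without transgenic old replicate 1). Of 15 called genes named in the text, 9 kept their call without each single library. Acox2, Adamts9, Ctla4, Fzd10, Nfe2 and Pou2af1 lost it without at least 1 of wild-type young DN3a replicates 1, 2 and 3, transgenic young DN3a replicates 1 and 2, wild-type old DN3a replicates 1, 2 and 3 and transgenic old DN3a replicates 2 and 3.

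A last comparison asks whether transgenic DN3a cells lie nearer to DN2 in expression. Genes at least 2-fold higher in wild-type DN2 than DN3a (277 genes, from the 5 young wild-type libraries) were higher in transgenic than wild-type old DN3a, with a median log2 fold change of 1.40, 194 called higher and 7 lower. Genes at least 2-fold higher in wild-type DN3a (172 genes) were lower there, with a median of -1.63, 7 called higher and 119 lower. Camera gave p = 6.91e-28 and p = 1.64e-24 for these 2 sets, which share no library with the comparison, and p = 0.065 and p = 0.0241 with an estimated correlation. Without wild-type DN2 replicate 1 the fit behind the sets called 0 genes, against 598, so the sets rest on that library. Made without each of the 4 others they kept their directions, with medians of 0.503 to 1.592 and -2.105 to -0.636. The wild-type DN2 over DN3a fold correlated across genes with the transgene's fold in old DN3a at r = 0.333 (rho 0.323, covariance 0.294). In young DN3a, whose control libraries are shared with the sets, r was 0.359. The shared controls alone gave r = 0.438 and a covariance of 0.069 in 100 simulations, against an observed covariance of 0.211, a difference of 0.142.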

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

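The tests chosen only after results were seen were those with the share of the unnamed feature as a covariate, those without male mice, the regrouping of ages within genotype, and the reading of lost calls by fold and SE; the rule that weighs the 2 tests of sex was also rewritten after its values were seen, and the bounds for female libraries alone were set then.

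The transgene's effect differed between DN2 and DN3a of young mice for 2828 genes by the interaction test of edgeR, a test of the difference itself. Values here are log2 differences of the transgene's effect, DN3a minus DN2. The genes with the largest positive differences were Tgfb2 (7.89), H2-Q2 (6.64), Rhbdl3 (5.65), Slc40a1 (5.44) and Pla2g4c (5.12). Slc40a1 encodes the iron exporter ferroportin and Tgfb2 a growth factor. Those with the largest negative differences were Lrrc25 (-9.51), Cd33 (-9.10), Gna15 (-6.52), Rnf180 (-6.32) and Itgax (-6.21), of which Cd33 and Itgax are myeloid surface proteins. The values of Tgfb2, Lrrc25, Cd33, Gna15 and Itgax rest on a group with at most 3 reads and are no bound on the difference. Without wild-type DN2 replicate 1, Tgfb2 (1.238) and Rhbdl3 (-1.664) lost their call, and Rhbdl3 its sign.

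The mitochondrial list, which holds 5 nuclear genes (median 2.86), G2 and M phase genes (2.81) and S phase genes (2.00) had the most positive differences. These lists were lower in transgenic DN2 but not in transgenic DN3a. The 15 genes on the mitochondrial chromosome alone had a median of 2.96. E protein regulated genes (1.39), MYC targets (1.14), beta selection genes (1.05), cholesterol synthesis (0.84), mature alpha beta T cell genes (0.49), ribosomal protein genes (0.44) and T lineage commitment genes (0.37) also differed upward. Myeloid genes (-2.78), NK and innate lymphoid genes (-1.49), interferon response (-1.47), stem and progenitor genes (-1.23), early T progenitor regulators (-1.23) and dendritic cell and MHC class II genes (-1.04) differed downward. All these lists passed camera at the preset correlation, and with an estimated correlation myeloid genes (adjusted p = 0.0317), dendritic cell and MHC class II genes (0.0443) and NK and innate lymphoid genes (0.0443) still did.

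The transgene's effect differed between old and young DN3a for 413 genes by the interaction test. The genes with the largest positive differences, old minus young, were Aif1l (7.73), Ephb4 (5.40), Adamts9 (5.28), Fzd10 (5.04) and Acox2 (4.92). Ephb4 encodes an ephrin receptor and Fzd10 a Wnt receptor. Those with the largest negative differences were Hoxa5 (-7.31), Tceal8 (-7.11), Pdgfa (-6.94), Tmtc2 (-6.79) and Prr33 (-6.64). The values of Aif1l, Hoxa5, Tceal8, Pdgfa, Tmtc2 and Prr33 rest on a group with at most 3 reads and are no bound. S phase genes (median 0.76) and G2 and M phase genes (1.22) differed upward by camera. The mitochondrial list, which holds 5 nuclear genes, differed downward (-1.31, or -1.49 for its 15 genes on the mitochondrial chromosome). With an estimated correlation camera gave adjusted p = 0.855, 0.855 and 0.855.

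In young DN2, 3426 genes differed between transgenic and wild-type cells. Cells past DN2 in the wild-type libraries would make genes low in transgenic DN2 higher still in wild-type DN3a. Across the called genes these differences correlated at 0.196 and 0.212, each against a separate wild-type library. This argues against such cells as the source of the called genes as a set. It leaves them open for T lineage genes such as Ptcra, which was lower in transgenic DN2 and rose to DN3a in wild-type cells. The 6 abundant transcripts of mature myeloid cells summed to at most 24.98 CPM in a transgenic library. That argues against mature myeloid cells but leaves myeloid progenitors untested. With the log2 share of the unnamed feature as a covariate 40.5% of the genes kept their call, fewer than the bound of 50% set beforehand for the share as the cause, yet the median absolute log2 fold change moved from 1.24 to 1.12 and its SE from 0.28 to 0.34, with 100% of directions kept, so calls ended with a slightly smaller fold and a larger error. Over the called genes the fold with the covariate had a median ratio of 0.91 to that without it. The genes were called in a fit of these same libraries, so a high ratio and kept directions are partly built in. The share is therefore left open as a source of the difference. The share and genotype run together in DN2 (0.972 and 10.95% of reads). The share of the feature and the transgene therefore cannot be told apart for the genes that lost their call. An effect of the transgene remains open as a hypothesis.

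In DN3a, 374 of the 413 genes of the interaction with age (90.6%) had the larger effect in old mice, and with the library letter as a covariate 90.8% of the 413 kept their call, which argues against the letter as the whole cause. With the share of the unnamed feature as a covariate 26.2% kept it, again under the bound set beforehand for the share as the cause, while the median absolute log2 difference moved from 2.44 to 2.27 and its SE from 0.51 to 0.58. With sex as a covariate 88.4% kept their call, which decides nothing. Each young DN3a group holds 1 male in 3 and all old mice were female, so sex cancels in the difference. In the female libraries alone 29.3% kept their call. The median there was 2.28 with an SE of 0.56, a median ratio of 0.94 to all libraries. The 413 genes were selected in a fit that includes these same female libraries, so a high ratio is partly built in. The rule for sex was rewritten, and the bounds for female libraries set, after their values were seen. A sex effect alike in both genotypes thus cancels by design, while one that differs between genotypes is left open as a source of the difference. Regrouping genotypes within age gave as many genes in 9 of 100 splits, up to 3346, but all of these kept the old genotypes apart and so carry the transgene's effect in old mice as a structure of the libraries, while the others gave at most 3, and chance is not excluded by this test, set beforehand; regrouping ages within genotype, chosen afterwards, gave as many in 3 of 100 splits, the real one included, with 430 as the highest other, but splits that kept the transgenic ages apart gave 174 to 430 and the others at most 9, so that count follows the transgenic ages and chance is left open for the wild-type part of the difference. Over the 413 genes, the difference with the share as a covariate had a median ratio of 0.95 to that without it. All directions (100%) were kept, but the 413 genes were called in a fit of these same libraries, so both values are partly built in. The share is therefore left open as a source of the difference. For genes that lost their call, the share of the feature and age itself cannot be told apart.

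For the other counts the 6 libraries compared make 10 splits, too few for a share under 0.05. The real split gave 1334 genes for transgenic against wild-type in young DN3a and the highest other 0, which was 1 of 10 splits as large, the real one. For old DN3a these were 4146 and 2, for DN3a against DN2 in transgenic cells 3506 and 0, and for age in transgenic DN3a 1059 and 0. For age in wild-type DN3a they were 33 and 75, so 2 of 10 splits were as large, and the other one follows the library letter, with which as a covariate the real comparison gave 77 genes. Comparisons that use the 2 wild-type DN2 libraries were not tested by splits.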

How the results depend on the processing

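The tests with the share of the unnamed feature as a covariate, without the libraries rich in it, without its reads, without male mice, with the correlation estimated for the stage sets, with stage sets made without single libraries, and without single libraries for the correlations of transgene effects were chosen after seeing the data. Where a value below moved, the cause was not tested unless given. RLE size factors, no filter on low counts, sex as a covariate, the block by mouse and the removal of the feature with Lars2 and mitochondrial genes left every count of changed genes they were run for within 1.5 times.

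Transgenic against wild-type young DN2 (3426 genes) gave 1413 with the share as a covariate, 1283 without the libraries rich in the feature, where fewer libraries are compared, and 1535 to 4297 without single libraries, with 1535 without wild-type DN2 replicate 1 and 2177 and 2261 without transgenic replicates 2 and 3. Young DN3a (1334) gave 3692 with limma voom, 2177 with a block by replicate number and 737 to 1376 without single libraries, with 782 and 737 without wild-type replicates 1 and 2. Old DN3a (4146) gave 3043 to 3924.

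DN3a against DN2 in wild-type cells (860) gave 1374 with DESeq2, 1644 with limma voom, 1529 with the library letter, 3514 with a block by replicate number, and 11 to 1689 without single libraries: 11 and 1689 without wild-type DN2 replicates 1 and 2, and 288 and 136 without DN3a replicates 1 and 2. In transgenic cells (3506) it gave 5874 with limma voom, 1731 without the libraries rich in the feature and 2511 to 3784 without single libraries. Its interaction with genotype (2828) gave 4571, 1307 and 1667 to 3584 in the same settings, with 1667 without wild-type DN2 replicate 1. Where 1 wild-type DN2 library is left, its spread is assumed to be that of the other groups.

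Age in wild-type DN3a (33) gave 125 with DESeq2, 274 with limma voom, 18 in a fit of its groups alone, 77 with the letter, 12 with the share, 14 without the libraries rich in the feature and 10 to 42 without single libraries: 10 without young replicate 1 or 2, and 20 and 16 without old replicates 2 and 3. Age in transgenic DN3a (1059) gave 1798 with limma voom, 494 with the letter, 415 without the libraries rich in the feature, 1780 with a block by replicate number and 456 to 1200 without single libraries. Its balance of 432 genes higher and 627 lower turned to 589 and 412 in a fit of its groups alone, to 979 and 801 with the block by number and to 889 and 909 with limma voom. Single libraries gave 456 without young replicate 1, and 502 and 467 without old replicates 2 and 3. The interaction of genotype and age (413) gave 738 with DESeq2, 642 with limma voom, 109 with the share, 128 without the libraries rich in the feature, 122 without male mice, 667 with a block by replicate number and 188 to 605 without single libraries. These were 188 and 264 without transgenic young replicates 1 and 2, 192 and 223 without transgenic old replicates 2 and 3, 246 and 245 without wild-type young replicates 1 and 2, and 247 and 252 without wild-type old replicates 1 and 2. In wild-type DN2 and DN3a, numbers 1 and 2 stand for the same mice (deviations correlated at 0.091 and 0.185), so that block by number is a block by mouse over 5 libraries, and a block by mouse over all young libraries gave 1001 genes against its 3514. Elsewhere numbers do not follow the mouse, and deviations of the same number correlated at -0.02 to 0.22 between genotypes and -0.28 to 0.32 between ages, over 0.1 in 4 of 8 and 3 of 6 pairs.

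Lists called by camera numbered 16, 11 and 5 for the genotype in young DN2, young DN3a and old DN3a, 10 and 16 for stage in wild-type and transgenic cells, 16 for its interaction, 5 and 6 for age and 3 for its interaction. With an estimated correlation these were 3, 1, 0, 0, 10, 3, 0, 0 and 0. With fry, old DN3a gave 15 lists, and age in wild-type cells and the interaction with age 0 each, and without a filter old DN3a gave 8. The set of genes higher in DN2 had p = 0.065 in old DN3a with an estimated correlation, and both sets passed in the same direction without each single old library, with RLE, without a minimum fold and without cell cycle and histone genes. Sets made without wild-type DN2 replicate 1 could not be tested, since 0 genes were called. Without each other young wild-type library, camera at the preset correlation gave the set higher in DN2 p = 4.36e-28 to 8.21e-08 and the other 1.67e-26 to 1.39e-09. With an estimated correlation these were 0.0867 to 0.278 and 0.0102 to 0.315. The correlation of transgene effects between young and old DN3a (0.618) was 0.747 over called genes and 0.541 to 0.669 without single libraries. Between young DN2 and young DN3a (0.214) it was 0.263 and 0.162 to 0.235. Between young DN2 and old DN3a (0.049) it ranged from -0.027 to 0.067, and reversed to -0.027 without wild-type DN2 replicate 2.

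The 269 values of named genes were refitted 4734 times under the alternatives. Direction and side of the threshold held in 4433, a call was lost in 288 and gained in 7, the sign changed in 6, and 184 of the 269 kept both throughout. Spi1 in young DN3a (not called) was 0.344 with limma voom, 0.335 with the letter and -1.377 to 0.613 without single libraries, with the positive value without wild-type young replicate 3. Igsf3 in DN2 (not called) ranged from -0.041 (without transgenic replicate 2) to 0.401 and Trim45 in young DN3a (not called) from -0.010 (without transgenic replicate 1) to 0.233. The interaction of Rhbdl3 with stage, which passed, ranged from -1.664 to 6.903 without single libraries, and lost both its sign and its call without wild-type DN2 replicate 1.

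Depth sets a floor: 1 read is 0.0880 to 0.139 CPM, so folds of genes silent in a group are bounds.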

Other observations

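The genes around Cd2 on chromosome 3 were looked at after the values of Cd2 were seen. In transgenic against wild-type young DN3a, Ptgfrn (4.69 ± 0.47), Cd2 (7.28 ± 0.55) and Igsf3 (3.07 ± 0.26), which lie side by side at 101040230 to 101110745, 101275908 to 101287939 and 101376672 to 101463060, were higher, and in old DN3a likewise (4.61 ± 0.47, 6.97 ± 0.57 and 2.30 ± 0.25). Ptgfrn and Igsf3 encode related immunoglobulin domain membrane proteins. Ttf2, further out at 100938860 to 100969700, was higher in young (0.75 ± 0.22) and old DN3a (1.5 ± 0.22) and lower in DN2 (-0.92 ± 0.24). Beyond it, Trim45 (0.13 ± 0.25 and 0.48 ± 0.25 in young and old) did not pass in edgeR. In DN2, Cd2 was higher (3.36 ± 0.60), while Ptgfrn (1.55 ± 0.63) and Igsf3 (0.15 ± 0.33) did not pass.

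Adamtsl2 and Fam163b, which lie next to each other on chromosome 2 at 27079336 to 27108981 and 27110379 to 27142477, were named together in 1 comparison, and reads between adjacent genes cannot be assigned with certainty where the strand is not given. In transgenic cells from DN2 to DN3a they rose by 68.5-fold, 23.4 to 332 and, on the log2 scale, 6.29 ± 0.95.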
